A study of Homo sapiens with 6 samples.

How the data were processed

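Poly(A)-selected RNA from 6 samples of human LNCaP prostate cancer cells was sequenced as 150 bp paired-end reads, per the labels' protocols. The 6 libraries fall into 2 groups of 3, named here LNCaP-WT and LNCaP-ENZR after the labels. RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build GRCh38, without versions or roles. The annotation release, the counting mode and the strand setting are not given in the sources used here. Whether the 3 libraries of a group came from separate cultures is not stated either, so p-values measure the spread between these libraries, which may be technical.

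The deposited tables hold 23998 gene symbols. The deposited count table holds raw counts per gene as the authors made it, with no normalization, and library totals between 34505712 and 36610862. The deposited FPKM table holds the authors' values per kilobase of gene model, scaled by each library's total counts. For 23998 of 23998 genes, the length implied by dividing counts by FPKM was the same in all libraries within 0.001%, so the FPKM values carry the same counts scaled by the totals. Those implied lengths served as gene lengths. Each column of both tables was tied to a library by its name.

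Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test (robust, two-sided) with TMM scaling and the default filter on low expression. The filter left 15422 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts with at least a 2-fold change are given beside it. Levels are CPM (counts scaled to a common library total) over TMM-scaled library sizes, as mean ± SD with n = 3. Log2 fold changes are LNCaP-ENZR over LNCaP-WT, with an SE derived from the F statistic. Where a group held fewer than 10 counts of a gene, a ratio given for it is that of scaled counts, with a 95% exact binomial interval. Such intervals cover counting error only.

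The comparison, its test, the named genes and 29 gene lists were fixed before the data were examined. Genes are named by 3 rules. The first is a fixed set of 16 genes of androgen signalling, mitochondrial regulation and common prostate cancer lesions. The second takes the 10 highest and 10 lowest called fold changes among genes with a mean of at least 100 counts, libraries that do not overlap between groups, and no locus-type, antisense, pseudogene or long non-coding name. The third takes up to 4 called members per list with the largest absolute fold change and a mean of at least 100 counts. Other list members appear where a list's spread or direction is described, and genes chosen after their values were seen are named as such. Some genes that these rules name are not reported here. The lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists with at least 5 tested members. Camera asks whether a list's members moved differently from all other tested genes. The older symbols of some list members were matched by hand, and mitochondrially encoded genes go by short names in the table, such as ND1 for MT-ND1.

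Coordinates come from a RefSeq gene table on GRCh38, the build the processing notes name. GC content was computed from GENCODE release 29 transcripts and was available for 13592 of the 15422 tested genes, 88.1%. Trends with length or GC content were fitted in each library as a smooth curve over genes outside 4 lists (OXPHOS and ribosome proteins) and removed as offsets in the same edgeR test.

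The alternatives were DESeq2 size factors (DESeq2 1.42.0), library totals alone, upper-quartile factors, leaving out mitochondrially encoded genes, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 50 counts), the DESeq2 Wald test, limma-voom, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1) for genes with an FPKM of at least 0.1 in 3 libraries, a replicate block, and each library left out in turn. Lists were also tested by camera with an estimated correlation and by fry. The length and GC offsets were chosen after seeing the data.

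The tests were tried on simulated data with the library sizes and dispersions of this comparison, over 15422 genes. At 1.25-fold, 1.5-fold, 2-fold and 4-fold changes edgeR recovered 40%, 72%, 82% and 100% of 50 changed genes each, with 10 false calls. Far fewer genes changed in the simulation than the 10674 called in the data, so these rates may differ there. Camera called a simulated list of 40 genes shifted by 0.4 on the log2 scale and 0 of 28 unshifted lists. Those simulated genes were drawn independently and no others were shifted, so this trial does not cover correlation among list members. With gene order shuffled over 12907 placed genes, the test of neighbouring genes found 0 outlying blocks, and it recovered 10 of 10 blocks shifted by 1 on the log2 scale. Figures were drawn with matplotlib 3.10.9.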

Results

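Transcript levels were measured by RNA-seq in LNCaP cells, an established human prostate cancer line that grows in response to androgens, and in an enzalutamide-resistant derivative of it, LNCaP-ENZR. Enzalutamide is an antiandrogen drug. Per the labels, the resistant cells were exposed to rising doses from 5 to 50 µM for over 12 months in medium with 10% charcoal-stripped serum, which is depleted of steroids, and the LNCaP-WT cells were untreated. The labels' growth protocol names 10% fetal bovine serum for all samples. They do not say whether the drug or the stripped serum was present at harvest, so drug history and serum are not separated by this design. With no further group, the time in culture during exposure also coincides with resistance. The libraries do not replicate the derivation of the resistant cells. Each group held 3 libraries, with total counts of 34505712 to 35531519 in LNCaP-WT and 35790974 to 36610862 in LNCaP-ENZR. The series addresses mitochondrial oxidative phosphorylation (OXPHOS) in cells under antiandrogen treatment.

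The resistant cells differed from the parental cells across most of the measured transcriptome. Of 15422 tested genes, 5308 rose and 5366 fell in LNCaP-ENZR by edgeR's quasi-likelihood test at an adjusted p under 0.05. With at least a 2-fold change, 1502 rose and 1830 fell. Among the called genes, 4496 changed by less than 1.5-fold. Over all 15422 tested genes, 11129 had libraries that did not overlap between the groups, which chance gives for 10% of genes. The first principal component held 85.0% of the variance and separated the groups. Spearman correlations between libraries ran from 0.975 to 0.976 within groups and from 0.948 to 0.949 between them. The biological coefficient of variation was 7.41%, and every pair of libraries of one group differed by more than sampling noise (chi-square per degree of freedom of 3.73 to 12.0).

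Genes for the subunits of the respiratory chain were modestly higher in the resistant cells. Of the 77 nuclear-encoded OXPHOS subunit genes, 65 rose, 1 fell and 11 did not pass, with a median log2 fold change of 0.45 and a mean of 0.42, or 1.34-fold. The largest rise was that of ATP5ME, a subunit of ATP synthase, from 65.4 ± 1.5 to 138.5 ± 11.1 CPM (SD, n = 3 per group; log2 fold change 1.08 ± 0.063 SE, edgeR adjusted p = 1.5e-11). NDUFB10, a complex I subunit, rose 2.07-fold, the ATP synthase c-ring gene ATP5MC1 rose 2.02-fold, and CYCS, which encodes cytochrome c, rose 1.98-fold. The exception was NDUFC2 of complex I, which fell from 24.5 to 15.9 CPM. By complex, 31 of 37 genes rose in complex I, 2 of 4 in complex II, 8 of 9 in complex III, 10 of 11 in complex IV and 13 of 15 in complex V. The list as a whole stood apart from other genes (camera adjusted p = 2.0e-09 with the preset correlation). That call was lost with an estimated correlation (adjusted p = 0.42), where the correlation among members came to 0.54. With offsets for gene length the list's mean log2 fold change was 0.33, and shorter genes tended upward in these libraries.

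**Figure D1:**
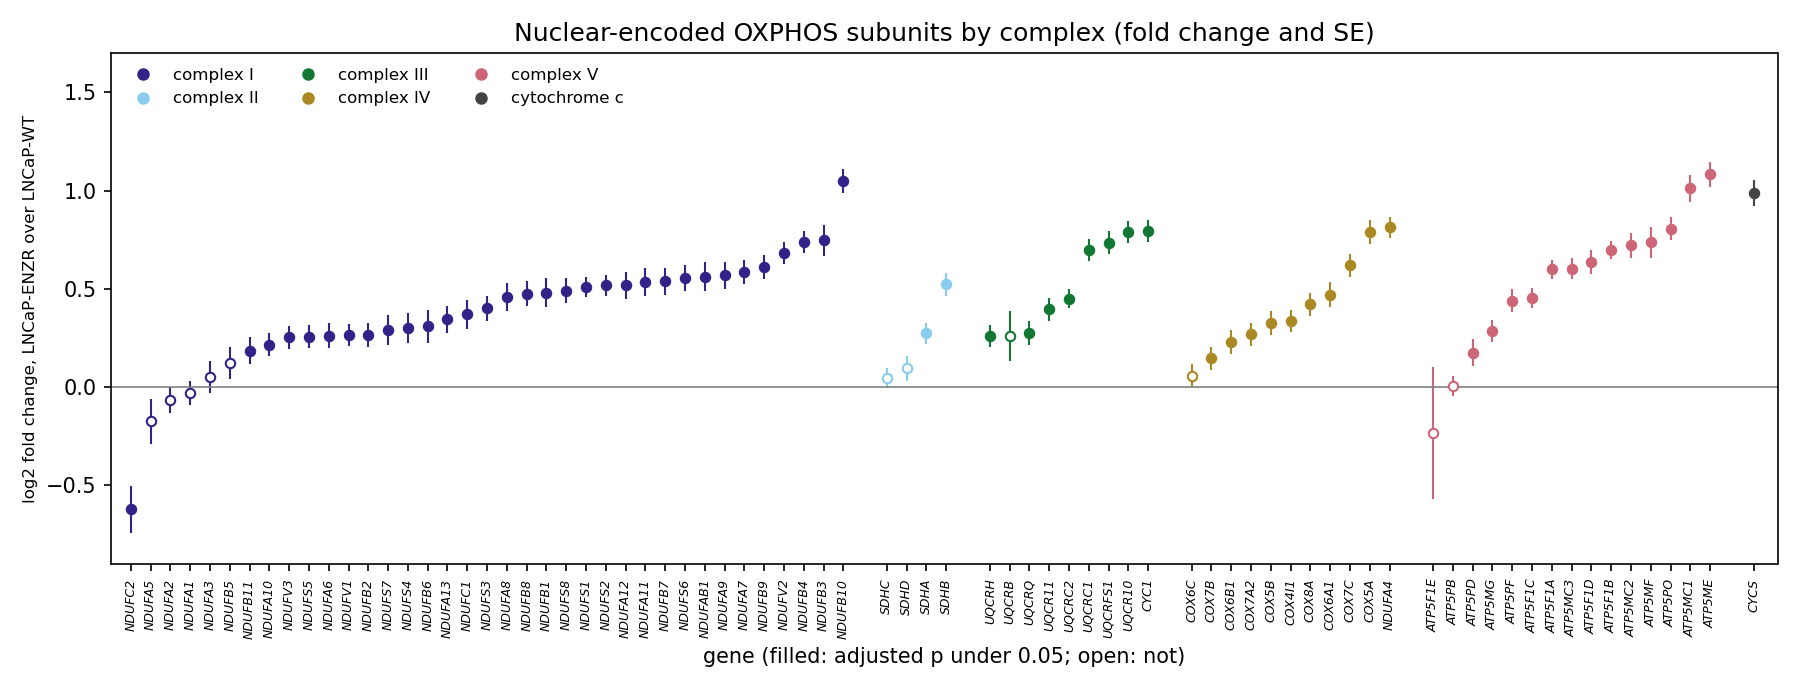
Log2 fold change (LNCaP-ENZR over LNCaP-WT) of each of the 77 nuclear-encoded OXPHOS subunit genes, grouped by complex, with bars for the SE (n = 3 libraries per group). Filled points passed an adjusted p of 0.05 in edgeR, and most lie between 0.1 and 1.08, with NDUFC2 the only filled point below 0.

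The 13 mitochondrially encoded subunit genes moved less. Of these, 11 rose and 2 did not pass, with a mean log2 fold change of 0.26. ND1 rose 1.34-fold, ND3 1.30-fold and ND4 1.248-fold, and ATP8 rose from 446 ± 94.5 to 695 ± 79.7 CPM (n = 3, edgeR adjusted p = 0.033). Together, mitochondrially encoded genes took 11.6 ± 0.149% of counts in LNCaP-WT and 13.1 ± 0.322% in LNCaP-ENZR (SD, n = 3). The list passed with the preset correlation (camera adjusted p = 0.024). It did not pass with library totals as the only scaling (adjusted p = 0.055), with limma-trend on log2(FPKM + 0.1) (adjusted p = 0.053), with offsets for gene length (adjusted p = 0.38) or GC content (adjusted p = 0.098), or with an estimated correlation (adjusted p = 0.42). Length offsets lowered the list's mean log2 fold change to 0.10, and with GC offsets it was 0.21. ATP8 shares bases with ATP6, so its value is uncertain. Its call was lost in 8 of the alternatives tried, among them those without LNCaP-WT 3 (edgeR adjusted p = 0.10), LNCaP-ENZR 1 (0.086), LNCaP-ENZR 2 (0.11) or LNCaP-ENZR 3 (0.081) and the fit with a replicate block (0.15).

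Other mitochondrial gene groups rose as well. Of 56 mitochondrial ribosome protein genes, 52 rose, 1 fell and 3 did not pass (mean log2 fold change 0.54, camera adjusted p = 2.9e-10, and adjusted p = 0.31 with an estimated correlation). MRPL11 rose 2.27-fold and MRPS17 2.21-fold. Among 19 genes of mitochondrial biogenesis, fusion and fission, 15 rose and 4 did not pass (camera adjusted p = 0.0036, and adjusted p = 0.15 with an estimated correlation). PPARGC1A, the coactivator that drives mitochondrial biogenesis, rose from 3.43 ± 0.321 to 17.2 ± 2.48 CPM (n = 3, log2 fold change 2.32 ± 0.13 SE, edgeR adjusted p = 1.2e-11). Its relative PPARGC1B rose 1.92-fold, SSBP1, which binds single-stranded mitochondrial DNA, 1.78-fold and the mitochondrial helicase TWNK 1.73-fold. TFAM, the main mitochondrial transcription factor, was at 51.3 ± 5.43 against 59.3 ± 4.32 CPM (n = 3, log2 fold change 0.21 ± 0.078 SE, edgeR adjusted p = 0.023), a call that 6 of the alternatives ended. Without LNCaP-WT 1, LNCaP-WT 3 or LNCaP-ENZR 1 the edgeR adjusted p for TFAM was 0.082, 0.12 and 0.071.

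Among 22 genes listed for the tricarboxylic acid cycle, 15 rose, 4 fell and 3 did not pass, with a mean log2 fold change of 0.25 (camera adjusted p = 0.022, and adjusted p = 0.21 with an estimated correlation). The list includes PDHA1, PDHB, DLAT and PC, which are not enzymes of the cycle itself and all rose. It shares SDHA, SDHB, SDHC and SDHD with the OXPHOS subunits. Citrate synthase (CS) rose 1.68-fold, fumarate hydratase (FH) 1.97-fold and DLAT of the pyruvate dehydrogenase complex 1.76-fold. IDH3A, a subunit of the NAD-dependent isocitrate dehydrogenase, fell 2.15-fold. Of 24 glycolysis genes, 14 rose, 5 fell and 5 did not pass, with a median log2 fold change of 0.37 and a mean of 0.69. LDHB rose from 324 ± 9.95 to 877 ± 30.9 CPM, hexokinase 2 (HK2) rose 2.40-fold and the regulatory enzyme PFKFB3 2.28-fold, while ENO2 fell 2.44-fold. The mean leans on the glucose transporter SLC2A3 and the lactate exporter SLC16A3, both scarce in LNCaP-WT at 0.00913 and 0.277 CPM. With SLC2A3 at its counting bound the mean was 0.60 and the median still 0.37. The glycolysis list passed at an adjusted p of 0.031, but not under the stricter filter (adjusted p = 0.072), with GC offsets (adjusted p = 0.062) or with an estimated correlation (adjusted p = 0.42). Fatty acid oxidation genes did not stand apart from other genes, with 5 of 19 genes higher, 7 lower and 7 not passing (camera adjusted p = 0.66). HADHB fell 2.03-fold and ACADVL 1.84-fold, and ECI2 rose 1.71-fold.

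Genes that respond to androgens went both ways. KLK3, which encodes prostate-specific antigen, fell 3.52-fold and KLK2 fell 1.31-fold. FKBP5, a cochaperone induced by both androgens and glucocorticoids, rose from 28.4 ± 0.469 to 102.4 ± 1.72 CPM (n = 3, log2 fold change 1.85 ± 0.062 SE, edgeR adjusted p = 4.0e-15). TMPRSS2 was 1.14-fold higher (edgeR adjusted p = 0.0024), a call that was lost with library totals as the only scaling (adjusted p = 0.073). Across 37 tested androgen-induced genes, 18 rose, 12 fell and 7 did not pass, and the list did not stand apart from other genes (mean log2 fold change 0.11, camera adjusted p = 0.38). TRPM8, a cation channel, fell 47.4-fold, from 25.9 ± 0.303 to 0.541 ± 0.156 CPM. CENPN, which rose 3.83-fold, is also a kinetochore gene.

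**Figure D2:**
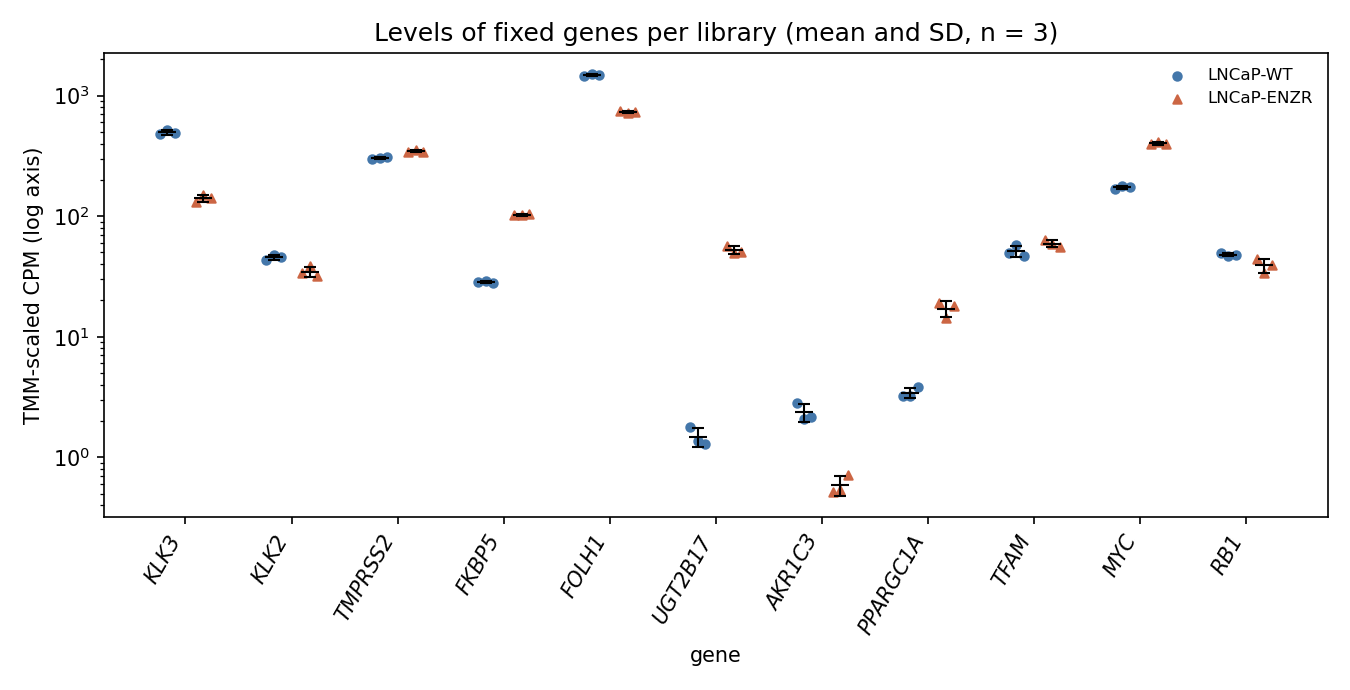
TMM-scaled CPM (log axis) of 11 of the fixed genes in each library, with LNCaP-WT as circles and LNCaP-ENZR as triangles, and black bars for the mean and SD (n = 3). FOLH1 lies at 1482 CPM in LNCaP-WT against 730.1 in LNCaP-ENZR, while UGT2B17 and PPARGC1A lie higher in LNCaP-ENZR, and NR3C1 is left out for too few counts.

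Androgen-repressed genes diverged. Of 11 tested members, 6 rose, 3 fell and 2 did not pass, with a median log2 fold change of 3.0 (camera adjusted p = 0.14). Members that fell included MET and LRRN1. The imprinted gene PEG10 rose from 0.129 ± 0.0782 to 22.05 ± 0.559 CPM. Genes for the UGT2B enzymes, some of which glucuronidate androgens and so inactivate them, rose from low levels. UGT2B15 went from 3.02 ± 0.255 to 284.9 ± 16.3 CPM, UGT2B17 from 1.48 ± 0.258 to 52.2 ± 4.01 CPM and UGT2B11 from 0.506 ± 0.146 to 133.8 ± 0.837 CPM (n = 3 each, edgeR adjusted p = 2.0e-17 for UGT2B17 and smaller for the other pair). These genes lie side by side on chromosome 4 and are closely similar in sequence, so the split of reads among them is uncertain. Across 16 tested genes of androgen synthesis and inactivation, 9 rose, 5 fell and 2 did not pass (camera adjusted p = 0.070, but under 0.05 in 7 of 20 camera alternatives, among them without LNCaP-WT 1 at 0.028), and 5 of the 9 that rose were UGT2B genes. AKR1C3, which makes testosterone from a weaker precursor, fell 3.98-fold, from 2.36 ± 0.4 to 0.590 ± 0.110 CPM, and it too has close relatives that can share its reads.

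The glucocorticoid receptor gene NR3C1 was near the limit of detection, with 2 counts over the 3 LNCaP-WT libraries and 9 over the 3 LNCaP-ENZR libraries, a ratio of 4.63 with a 95% counting interval of 0.959 to 44.1. Of 12 tested glucocorticoid receptor targets, 7 rose, 4 fell and 1 did not pass (camera adjusted p = 0.35). Apart from FKBP5, CEBPD rose 2.26-fold, whereas DUSP1 fell 2.26-fold and HSD11B2, which inactivates cortisol, fell 1.90-fold.

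Among luminal prostate markers, 5 of 17 rose, 9 fell and 3 did not pass (mean log2 fold change -0.56, camera adjusted p = 0.12). Prostatic acid phosphatase (ACP3) fell 12.3-fold, AMACR 7.10-fold and GATA2 2.32-fold, and FOLH1, which encodes prostate-specific membrane antigen, fell from 1482 ± 23.3 to 730.1 ± 12.0 CPM, though it shares sequence with its near-identical relative FOLH1B. Neuroendocrine markers were few, with 14 of 20 in the table and 5 tested, of which 2 rose, 2 fell and 1 did not pass (camera adjusted p = 0.72). DLL3 rose 1.5-fold and ENO2 fell 2.44-fold. Of 5 tested basal markers, 3 fell and 2 did not pass (camera adjusted p = 0.20), with the integrin gene ITGB4 4.34-fold lower and the laminin gene LAMB3 2.79-fold lower. Of 12 tested mesenchymal markers, 6 rose and 6 did not pass (camera adjusted p = 0.12), with LOX, a collagen cross-linking enzyme, at 0.580 ± 0.201 against 15.0 ± 0.750 CPM and VIM 1.40-fold higher.

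Marker lists of other cells did not stand apart from other genes where they could be tested. In genes typical of the prostate cancer lines PC-3 and DU145, 2 rose, 2 fell and 4 did not pass (camera adjusted p = 0.70), and the mean log2 fold change of 0.09 differed in sign from the median of -0.08 and from the direction camera gave. MET fell 2.52-fold and EGFR 1.22-fold. Of 8 tested endothelial and fibroblast markers, 2 rose, 2 fell and 4 did not pass (camera adjusted p = 0.93). VWF rose from 0.701 ± 0.451 to 31.3 ± 2.04 CPM, and TAGLN fell 2.69-fold. Leukocyte markers were too scarce for a list test. Their 10 measured genes summed to 15.4 ± 0.910 and 17.2 ± 1.79 CPM (SD, n = 3), nearly all of it from CD68, a lysosomal gene that is not confined to leukocytes.

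Genes of the cell cycle were higher in the resistant cells almost without exception. Of 32 proliferation genes, 31 rose and 1 fell, with a median log2 fold change of 1.48. The mitotic kinase genes AURKB and PLK1 rose from 17.1 ± 0.423 to 72.4 ± 3.45 CPM and from 32.2 ± 1.40 to 128.2 ± 3.72 CPM, the mitotic cyclin CCNB2 rose 3.96-fold and MCM2, part of the replicative helicase, 3.69-fold (n = 3, edgeR adjusted p from 7.9e-15 to 1.6e-15). The exception was CCNE2, which went from 27.0 to 16 CPM. This list gave a camera adjusted p of 7.1e-13, and it was the only list to pass with an estimated correlation (adjusted p = 0.028). MYC rose 2.31-fold, from 173.9 ± 5.44 to 401.3 ± 8.48 CPM. The tumour suppressor gene RB1 fell 1.23-fold (edgeR adjusted p = 0.0040).

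All 66 cytosolic ribosome protein genes rose, by a mean log2 fold change of 0.83 (camera adjusted p = 1.1e-16, and adjusted p = 0.42 with an estimated correlation). RPS12 rose 2.59-fold and RPSA 2.48-fold, though many of these genes have processed pseudogenes that share their reads. Among 13 tested replication-dependent histone genes and nuclear-retained RNAs, which are sensitive to RNA preparation, 11 fell, 1 rose and 1 did not pass (mean log2 fold change -1.17, camera adjusted p = 6.3e-04, and adjusted p = 0.15 with an estimated correlation). H2BC5 fell 5.47-fold and H2BC21 5.39-fold, and the nuclear RNAs MALAT1 and NEAT1 had log2 fold changes of -1.71 and -1.11. Short genes also tended upward. Across genes, the Spearman correlation of log2 fold change with gene length was -0.11, and the median ran from 0.22 in the shortest decile to -0.14 in the longest, although genes are not independent replicates. These shifts in RNA class and length stood beside the rise of the OXPHOS and ribosome genes. Of 12 common reference genes, 6 rose, 4 fell and 2 did not pass (camera adjusted p = 0.38), with PPIA 2.502-fold and GAPDH 1.76-fold higher and B2M 2.57-fold lower, and PPIA and GAPDH also have many processed pseudogenes.

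**Figure D3:**
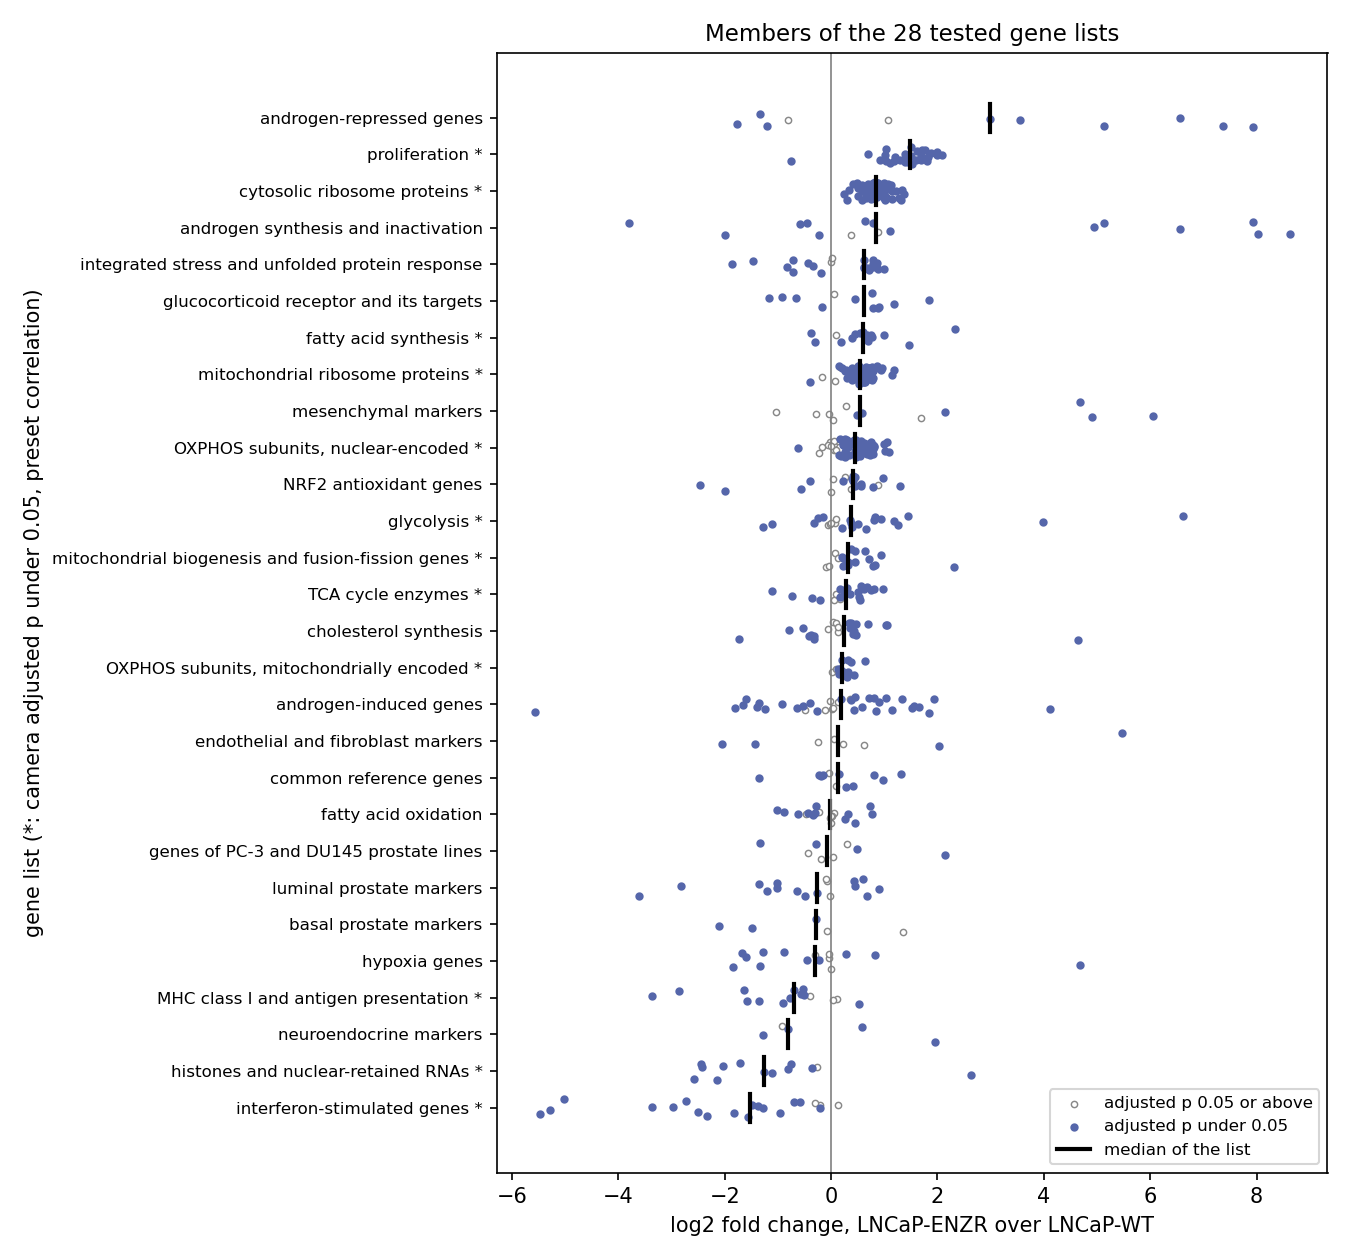
Log2 fold change (LNCaP-ENZR over LNCaP-WT) of every tested member of the 28 tested gene lists, one point per gene, with filled points at an edgeR adjusted p under 0.05 and black bars for the list medians. Proliferation genes centre on 1.48 and cytosolic ribosome genes on 0.84, whereas interferon-stimulated genes centre on -1.52.

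Interferon-stimulated genes and genes of antigen presentation were lower in the resistant cells. Of 20 tested interferon-stimulated genes, 17 fell and 3 did not pass, with a median log2 fold change of -1.52 (camera adjusted p = 3.1e-06, and adjusted p = 0.077 with an estimated correlation). The antiviral genes RSAD2, IFIT3 and OASL fell 44.4-fold, 39.2-fold and 32.5-fold, with 16 counts of RSAD2 left over the LNCaP-ENZR libraries, and IFIT2 fell from 34.2 ± 2.38 to 3.33 ± 0.167 CPM (n = 3, log2 fold change -3.36 ± 0.10 SE, edgeR adjusted p = 1.4e-15). Of 15 genes of the MHC class I pathway, 11 fell, 1 rose and 3 did not pass (mean log2 fold change -0.97, camera adjusted p = 0.0046, and adjusted p = 0.15 with an estimated correlation). ERAP1, which trims peptides, fell 3.13-fold, TAPBP, which helps load them, 2.99-fold, the light chain gene B2M 2.57-fold and HLA-B 1.88-fold.

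In lipid metabolism, 12 of 15 fatty acid synthesis genes rose, 2 fell and 1 did not pass (mean log2 fold change 0.62, camera adjusted p = 0.0039, and adjusted p = 0.21 with an estimated correlation). ELOVL6, an elongase, rose from 25.3 ± 0.369 to 126.8 ± 2.55 CPM and the desaturase FADS2 from 347 ± 10.0 to 957 ± 28.1 CPM. Of 24 cholesterol synthesis genes, 12 rose, 7 fell and 5 did not pass (camera adjusted p = 0.19). Adjusted over the list alone, 13 of these rose, and for the other 27 lists the counts adjusted over the list alone equalled those over all tested genes. FDPS rose 2.06-fold and EBP 2.06-fold, and SC5D fell 3.30-fold. Stress lists split. In the integrated stress and unfolded protein responses 12 of 22 rose, 8 fell and 2 did not pass (camera adjusted p = 0.37), with the amino acid transporter SLC7A5 1.99-fold higher and the chaperone DNAJB9 3.62-fold lower. Of 20 tested NRF2 antioxidant genes, 11 rose, 4 fell and 5 did not pass (camera adjusted p = 0.10), with NQO1 2.44-fold higher and GCLC, which limits glutathione synthesis, 5.52-fold lower. Of 15 tested hypoxia genes, 3 rose, 8 fell and 4 did not pass (camera adjusted p = 0.077, but 0.033 with limma-voom and 0.043 with length offsets), with LOX 25.7-fold higher and CA12 3.59-fold, BNIP3L 3.18-fold and NDRG1 3.04-fold lower.

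The largest changes were switches between near absence and clear expression. ALDH1A1, which oxidizes retinaldehyde, had 2 counts over the LNCaP-WT libraries and 1360 over the LNCaP-ENZR libraries, a scaled ratio of 700.2 with a 95% counting interval of 193.5 to 5787. ADARB2, UGT2B10, RND3, CTAG2, UGT2B11, ST6GALNAC1, UGT2B28, PEG10 and RALYL made up the rest of the 10 highest, and RALYL, the last of them, had a scaled ratio of 134.9 with an interval of 65.2 to 336. CTAG2 has a closely similar relative, CTAG1B, and its counts are uncertain. In the other direction, LRRTM3, a synaptic adhesion gene, had 2598 counts in LNCaP-WT and 2 in LNCaP-ENZR, a scaled ratio of 1262 with an interval of 349 to 10423. The neuropeptide gene NTS went from 3477 to 5 counts, a ratio of 675 with an interval of 289 to 2081, and CTNNA3, an alpha-catenin, from 4119 to 8, a ratio of 500.1 with an interval of 254 to 1159. LRRTM3 (chromosome 10, 66926036 to 67101551) lies inside the span of CTNNA3 (65912523 to 67763594), and reads of overlapping genes cannot be told apart where the strand setting is not given. CD274, which encodes the immune checkpoint ligand PD-L1 (chromosome 9, 5450542 to 5470554), fell from 65.7 ± 0.356 to 0.589 ± 0.163 CPM (n = 3, log2 fold change -6.79 ± 0.13 SE, edgeR adjusted p = 1.1e-18). The splicing regulator MBNL2 fell 117.6-fold, from 1497 to 12 counts, and GNAT3, RAI2, APOL1, APOL6 and VWA5B1 completed the 10 lowest, with VWA5B1 50.1-fold lower.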

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

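The length and GC offsets were chosen after seeing the data. Over 19 alternatives for each count of called genes, 37 of 38 values stayed within 1.5 times the count reported, and 1 moved: with limma-trend on log2(FPKM + 1), 1224 genes passed with a 2-fold change against 3332, where the pseudocount shrinks the folds of low genes by construction. For the 28 lists, 537 of 583 alternatives kept direction and side of the threshold, 17 lost the call, 25 gained one and 4 changed direction. For the 125 named genes the numbers were 2351 of 2371 kept and 20 lost, all of TMPRSS2, TFAM, ATP8 and CD68 (for CD68, adjusted p = 0.079 without LNCaP-ENZR 2). No single library left out ended a list's call, and 2 lists that had missed the threshold passed it when a library was left out: androgen synthesis without LNCaP-WT 1 (0.028) and mesenchymal markers without LNCaP-ENZR 1 (0.037). With an estimated correlation the adjusted p was 0.422 for nuclear-encoded OXPHOS subunits, mitochondrially encoded subunits and glycolysis and 0.213 for the tricarboxylic acid cycle. Camera then uses the members' own correlation and also only the residual degrees of freedom of 6 libraries, and for the tricarboxylic acid cycle that correlation was 0.0047, under the preset 0.01. These were the highest adjusted p values over the camera alternatives of each list, and the lowest by camera were 1.4e-12, 0.0039, 0.0066 and 0.0053. The mitochondrially encoded list also missed the threshold with library totals alone (0.0550), FPKM + 0.1 (0.0534), length offsets (0.377) and GC offsets (0.0985), and glycolysis missed it with the stricter filter (0.0722) and GC offsets (0.0624). The cause was not tested. Fry asks only whether members move one way on balance, not whether they differ from other genes, and called 26 of the 28 lists, 14 of them lists that camera did not call. Those 14 included androgen-induced genes (0.00201), androgen-repressed genes (3.29e-06), neuroendocrine markers (0.0240), fatty acid oxidation (0.039) and the common reference genes (0.0057). By camera, limma-voom and length offsets called hypoxia genes (0.033 and 0.043), and FPKM + 1 called androgen-repressed genes (0.0465). Direction changed for fatty acid oxidation without a filter (0.955) and for genes of PC-3 and DU145 with the stricter filter (0.562), FPKM + 0.1 (0.806) and FPKM + 1 (0.831), none of them near a call, and the cause was not tested. Library totals alone moved the median of all genes by -0.086 and no other scaling by more. The replicate numbers share no stated origin, and same-numbered libraries deviated together with correlations of only 0.013, 0.027 and 0.065. A replicate block called 10714 genes, 3345 of them with a 2-fold change, and among named genes it ended only the call of ATP8. Not every library correlated best with its own number. Low counts limit the folds of genes near absence in one group. Counting intervals were computed only for groups with fewer than 10 counts, so folds such as those of MBNL2 (12 LNCaP-ENZR counts) and RSAD2 (16) are fitted values without one.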

Other observations

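The neighbouring genes and the genes of interferon signalling (JAK1, JAK2, IRF1 and IFNAR1) named first, the length and GC offsets, and the counts of list members inside outlying blocks and of genes above 0 per chromosome were chosen after the results were seen. Some of the genes that fell the most have neighbours that also fell, counted here over the 6 nearest tested protein-coding genes on each side. Such counts were made only around CTNNA3, CD274 and MBNL2. Over all 15422 tested genes, 5366 fell and 5308 rose. On chromosome 10, DNAJC12 (67796669 to 67838188), SIRT1 (67884656 to 67918390) and HERC4 follow CTNNA3 and LRRTM3 among the tested protein-coding genes. DNAJC12 fell from 88.8 ± 6.24 to 9.11 ± 0.417 CPM, SIRT1 fell 3.18-fold and HERC4 1.72-fold. On the other side the nearest genes, REEP3 and JMJD1C, fell less (log2 fold changes of -0.27 and -0.34). Leaving out LRRTM3, which lies inside CTNNA3 and can share its reads, 7 of the other 11 neighbours of CTNNA3 fell, 3 rose (NRBF2, RTKN2 and ADO, by 0.54, 0.46 and 0.26) and 1 did not pass. On chromosome 9, JAK2 (4984390 to 5129948) and PLGRKT come just before CD274. JAK2 fell from 54.4 ± 3.06 to 6.93 ± 1.47 CPM (n = 3, log2 fold change -2.97 ± 0.12 SE, edgeR adjusted p = 4.5e-13) and PLGRKT fell 3.13-fold. CDC37L1, which fell 3.88-fold, is set apart from JAK2 by AK3 and RCL1, with log2 fold changes of -0.41 and -0.34. Directly beyond CD274, RIC1, ERMP1 and RANBP6 fell (-0.85, -0.25 and -0.27). Of the 12 neighbours of CD274, 10 fell and 2 rose (UHRF2 and GLDC, by 0.59 and 1.79). Around MBNL2 on chromosome 13, the adjacent genes HS6ST3 and RAP2A fell (-2.38 and -0.996), as did UGGT2 (-0.97) and DNAJC3 (-0.34), while 5 of the 12 neighbours rose, ABCC4 and IPO5 the most (1.56 and 1.26), and 3 did not pass. The 4 of 12 that fell around MBNL2 are near the share over all tested genes, so falling neighbours were not in excess there. The blocks of 50 neighbouring genes that hold CTNNA3, CD274 and MBNL2 had median log2 fold changes of -0.12, -0.024 and 0.16, none of them outlying in the test of blocks. JAK2 and JAK1 are kinases of interferon signalling, and JAK1 fell 1.90-fold. IRF1, a transcription factor that interferons induce, fell 4.03-fold, whereas the receptor gene IFNAR1 did not pass (93.2 ± 1.17 against 88.6 ± 7.49 CPM).

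Neighbouring genes changed together over whole chromosome segments. Of 246 blocks of 50 neighbouring genes, 14 had a median log2 fold change outside the range that held all but 0.1% of block medians under shuffled gene orders (-0.39 to 0.40), against at most 2 in 1000 shuffles. Lower blocks included 85318485 to 98760500 on chromosome 1 (median -0.86), and higher ones 19633659 to 32538868 on chromosome 13 (0.58) and 20286227 to 23560271 on chromosome 14 (0.59), where 71.5% of the chromosome's genes were above 0 against 49.4% elsewhere. Removing GC trends left 15 such blocks against at most 3 in shuffles, which argues against GC content as the whole cause. Segments that differ between the cells, in copy number or as a shared regulatory domain, may explain the pattern, and RNA counts cannot separate these.

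The fall of interferon-stimulated genes is a second pattern. After GC offsets their mean log2 fold change was -2.01 against -2.00 before. Over all tested genes with a GC value, median log2 fold changes per decile of GC content ran only from -0.13 to 0.11. Offsets of that size could not have removed this fall, so it is the small size of the trend that argues against GC content. Leukocytes in the LNCaP-WT cultures are argued against as well, since PTPRC, LYZ and CD14 together reached at most 0.619 CPM in a LNCaP-WT library, under the bound of 1 CPM set before. Of 19 members with a position, 18 lay outside the 14 outlying blocks, with a median of -1.47 there. Only 14 of 246 blocks were outlying, so few members of any list would lie in them and the share inside is no test. The median shows that the fall was present outside those blocks. JAK1, a kinase of interferon signalling, does lie in an outlying block (chromosome 1, 63774017 to 85276632, median -0.60). Member positions cannot show whether such a gene carries the effect of a block to the list, and that was not tested. A difference between the resistant and parental cells themselves and one of serum or drug at harvest both stay open and were not tested.

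The higher OXPHOS subunit genes were weighed against length, gene class and scaling. With length offsets the list's mean was 0.331 ± 0.0343 (SE over 77 members) against 0.42 without, so those offsets removed only part of the observed shift. That SE treats members as independent, whereas their estimated correlation was 0.54. It is therefore too small to decide whether the rest lies beyond chance. The lowest mean over the scalings tried was 0.338, so none of those removed the shift. Library totals alone moved the median of all genes by only -0.086 and no other scaling by more, so a larger scaling difference was not tested. Against 10000 random lists matched on length, GC content and expression, with OXPHOS and ribosome genes left out, the list's median of 0.45 lay at the 96.5th percentile. Genes of the random lists were drawn independently, so their spread may be too narrow for a list of correlated members. The matched lists themselves had a middle value of 0.29 and a 95% range of 0.12 to 0.47, and the percentile fell between the bounds of 95 and 99 set before. A shift shared by short, abundant transcripts as a class may therefore make up part of the rise, and a change specific to OXPHOS genes cannot be told apart from it here.

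With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 10674 genes, and 3332 with a 2-fold change, and the highest of the other splits called 0 in both cases by edgeR, so 1 of the 10 splits gave as many genes. At an unadjusted p under 0.05 the other 9 splits gave 31 to 101 genes and the real split 10997. Each of those 9 splits put libraries of both groups on each side. The group difference then enters the spread within a side and lowers the calls, so these splits give no chance level for the real one.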
